A study of Mus musculus with 4 samples.

How the data were processed

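Single-cell RNA sequencing was performed on subcutaneous tumours grown in C57BL/6J mice from MC38 cells, a mouse colon carcinoma line, in which Hnrnpa2b1 had been knocked out (KO) or left in place (WT). Hnrnpa2b1 encodes an RNA-binding protein of the hnRNP family. There were 2 tumours in each group and 4 libraries in all. Tumours were minced, digested with collagenases, dispase and DNase and strained, with no sorting step stated, per the labels' protocols. The labels number the tumours 1 and 2 within each group and do not say what a number shares, so p-values for genes and cell shares measure the spread between these tumours.

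The deposited files hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, from the 10x Genomics droplet method. Reads were aligned to mm10 with Cell Ranger 5.0.1, per the labels' protocols, whereas the file headers of the matrices name Cell Ranger 6.1.2. The submitters' processing notes also name Seurat 5.1.0, without its role. Each file lists 55450 features, and 100% of their identifiers were found in the GENCODE vM21 annotation of GRCm38, from which coordinates were taken. Position and sequence of the edit in Hnrnpa2b1 are not given in the sources used here, so a UMI count of this gene need not fall where an edit leaves the transcript in place.

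Libraries held 12741 and 11628 barcodes in WT tumours 1 and 2, and 9547 and 9578 in KO tumours 1 and 2. Barcodes with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. The lowest UMI number of any barcode in each library was 500 or 501, so the UMI minimum removed no barcode. Doublet scores came from Scrublet, run through scanpy 1.11.5 in Python 3.11.15. The highest-scoring cells were removed at 0.8% per 1000 barcodes of a library, which took 1288 and 1043 cells from the WT libraries and 715 and 728 from the KO libraries. Scrublet's own threshold marked 2.84% and 0% of cells in the WT libraries and 3.63% and 4.5% in the KO libraries, and was not used. The cells analysed numbered 11344, 10173, 8648 and 8771.

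Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells of all libraries were clustered together without batch integration (15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2). Clusters were named from marker lists. A marker counted when at least 10% of the cluster's cells held it and its mean was at least 2 times that of the other cells, and 3 markers were needed. Clusters with more than 50% of cells of high doublet score, clusters led by markers of another class, and clusters of few UMIs with no marker among the 10 leading genes stayed unnamed. Cells of the T and NK lineage were clustered again in the same way. Class names below mean cells like that type by these markers.

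Epithelial markers fixed for the tumour cells were nearly absent. Of 12 markers, Msln was found in 38.7%, 32.1%, 66.2% and 66.3% of the cells concerned in WT tumours 1 and 2 and KO tumours 1 and 2, and each other marker in at most 4.49%. No cluster could be named tumour-like. In place of that class, clusters with a mean under 1 Xist UMI and under 1 Ptprc UMI per 10000 were joined as Xist-low cells. This rule was set after the data were seen. Xist is an RNA expressed from the inactive X chromosome of female cells, and Ptprc encodes the leukocyte antigen CD45.

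UMI counts were summed per tumour and class, and sums were tested between groups with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr) in R 4.3.3, with a separate fit for each class over 4 sums. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Classes with at least 50 cells in each tumour were tested. Levels are given as CPM, the count of a gene scaled to a common total by edgeR after TMM, unless stated. Cell numbers per class were tested with the same edgeR test, with the tumour's total as library size and no TMM. An exact permutation test of 2 against 2 tumours cannot go below 0.333. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a class. This test compares the genes of a list with the other genes and takes them as nearly independent. Its p-values therefore do not measure the spread between tumours alone, and are too small where members of a list vary together. Camera with an estimated correlation and the directional fry test were alternatives. With 4 tumours both rest on few degrees of freedom and have little power, so failing them does not show that a list was unchanged.

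The edgeR steps were tested on simulated counts with 200 changed genes, all drawn from genes with a mean of at least 10 CPM. Recovery below that level was therefore not measured. Each gene was given the dispersion of the fitted trend. For Xist-low cells, over 17680 genes, 53.2% of genes changed 1.5-fold, 98.3% of those changed 2-fold and 100% of those changed 4-fold were recovered. For mononuclear phagocytes, over 13238 genes, these shares were 18.3%, 78.6% and 100%. For CD8 T cells, over 10037 genes, they were 6.9%, 21.4% and 84.5%. False calls made up 6.9%, 9.3% and 5.5% of the calls for Xist-low cells, mononuclear phagocytes and CD8 T cells.

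The rule for named genes, the marker lists, 30 gene lists, cell filters, tests and most alternatives were fixed before the data were examined. In each main class the rule names Hnrnpa2b1, then the genes with the greatest rise and fall among those past the threshold with a log2 mean CPM of at least 4 and both KO tumours beyond both WT tumours (10 each way in Xist-low cells, 5 each way in the others). It leaves out Gm-numbered and Rik names, mitochondrial and ribosomal protein genes, Xist and Y-linked genes. From each list it adds up to 4 called members of smallest p, or 1 member where none was called. Some genes that the rule names are not reported here.

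Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a replicate block, leaving out each tumour, keeping doublets, a stricter cell filter (1000 genes, 10% mitochondrial), Leiden resolution 2.0 and equal numbers of cells per tumour. Added after the data were seen were subtraction of free RNA, leaving out clusters with a median under 2000 UMIs, a crossed replicate block, the test of differences between classes and the mixed fry test. Free RNA was taken as the profile of all barcodes of a library, scaled by genes the class should lack: immune markers for Xist-low cells, and for the other classes 30 genes enriched in Xist-low cells. Where cells were compared at equal depth, each was thinned to a fixed number of UMIs and shallower cells were left out.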

Results

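The tumours from Hnrnpa2b1-KO and WT MC38 cells were compared to ask how loss of this RNA-binding protein in the injected cells goes with the state of those cells and of the immune cells around them. Each group held 2 tumours. The libraries held 153162562 and 123655955 UMIs in WT tumours 1 and 2, and 114136609 and 132490304 in KO tumours 1 and 2, with median UMIs per barcode of 10384, 7972, 5779 and 5854.5.

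Cells fell into Xist-low cells, mononuclear phagocytes, T and NK cells, neutrophils, fibroblasts, and smaller groups of dendritic, endothelial, mural and mast or basophil cells. The Xist-low class stands in place of a tumour-like class, since the epithelial markers fixed for tumour cells were nearly absent, and its rule was set after the data were seen. Different clusters held it in the 2 groups. Cluster 1, led by Gja4, Nppb and Tubb3, held 76.6% and 77.6% of Xist-low cells in the KO tumours and 7.7% and 9.4% in the WT tumours. Cluster 0, led by Lbp, Prelp and Aldh3a1, held 24.4% and 28.2% in the WT tumours and 1.5% and 1.3% in the KO tumours. Cluster 4, led by Tnnt2, Cst6 and Rbp2, held 34.4% and 16.1% in the WT tumours and 2.6% and 3.6% in the KO tumours.

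Hnrnpa2b1 RNA was lower, not absent, in Xist-low cells of the KO tumours. The gene (ENSMUSG00000004980) lies on the minus strand of chromosome 6, from 51460932 to 51469894 in GRCm38, with 13 annotated transcripts and 34 distinct exons. Its level in Xist-low cells was 563 and 553 CPM in the WT tumours against 359 and 325 CPM in the KO tumours, a log2 fold change of -0.70 with a standard error of 0.13 (edgeR adjusted p = 0.0284). In mononuclear phagocytes, which come from the host, it was 399 and 425 CPM against 402 and 344 CPM (log2 fold change -0.14, standard error 0.20, adjusted p = 0.671). In CD8 T cells it was 658 and 678 CPM against 611 and 565 CPM (log2 fold change -0.18, standard error 0.20, adjusted p = 0.691). Some other classes were also lower in both KO tumours than in either WT tumour, by CPM without TMM. Fibroblasts held 367 and 361 against 309 and 294 CPM, and neutrophils 439 and 426 against 362 and 321 CPM. By this measure mononuclear phagocytes held 411 and 431 against 400 and 328 CPM. Dendritic, endothelial and regulatory T cells were also lower in both KO tumours. The groups overlapped in NK cells (466 and 566 against 484 and 441 CPM), CD4 T cells and gamma-delta T cells. They also overlapped, by this measure, in CD8 T, mural and mast or basophil cells. The difference between the change in Xist-low cells and that in mononuclear phagocytes was -0.53 with a standard error of 0.19, and did not pass (adjusted p = 0.0835). With a replicate block the change in Xist-low cells was -0.71 and did not pass (edgeR adjusted p = 0.0501). The call in Xist-low cells was lost without KO tumour 1 (log2 fold change -0.78, adjusted p = 0.0948) and without KO tumour 2 (-0.63, adjusted p = 0.168).

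At least 1 Hnrnpa2b1 UMI was found in 93.3% and 90.9% of Xist-low cells of the WT tumours and in 91.9% and 87% of those of the KO tumours, with median UMIs per cell of 11902 and 11701 against 38655 and 31538. Thinned to 1000 UMIs per cell, the shares were 37.9% and 38.1% against 29.8% and 24.3%, with 217, 277, 48 and 104 shallower cells left out. In mononuclear phagocytes, thinned alike, they were 31.4% and 32.6% against 33.1% and 30.1%. Xist-low cells deep enough to be thinned to 30000 UMIs, a depth chosen after the data were seen, numbered 293 and 413 in the WT tumours and 906 and 1473 in the KO tumours, leaving out 8289, 6680, 460 and 1196. At most 4 Hnrnpa2b1 UMIs were held by 2.0% and 1.7% of these cells in the WT tumours and by 29.8% and 34.6% in the KO tumours. Of the KO cells, 98 and 184 held 5 to 7 UMIs, near the boundary. Those with 8 or more had a median of 15 and 13 UMIs, against 16 and 18 in the WT tumours. No class lacked Hnrnpa2b1 RNA, and free RNA was estimated to add 2.0 and 1.03 UMIs per thinned cell in the WT tumours and 0.56 and 0.46 in the KO tumours. For Hnrnpa3, a related gene, the shares with at most 4 UMIs were 25.9% and 16.9% in the WT tumours and 8.1% in each KO tumour.

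**Figure D1:**
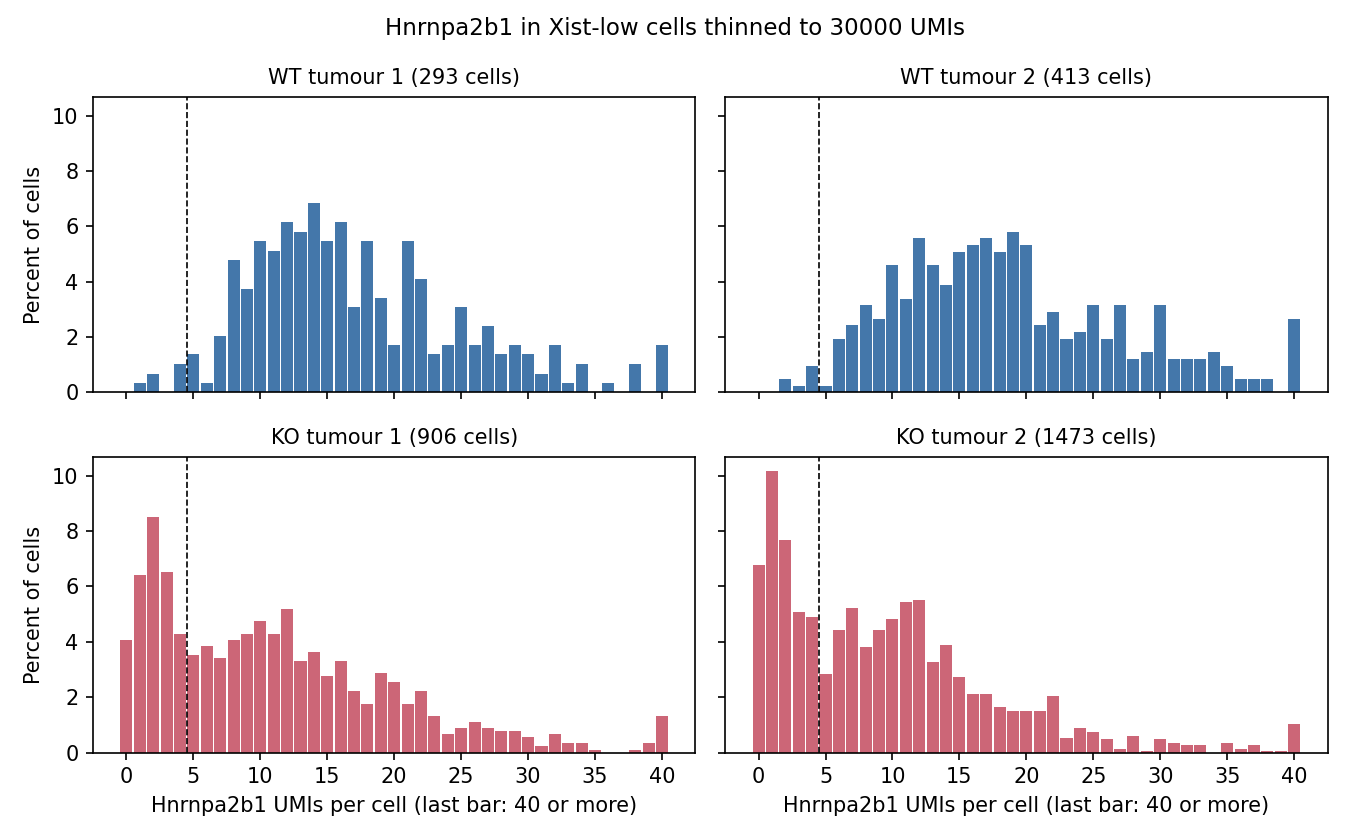
Percent of Xist-low cells (y axis) by number of Hnrnpa2b1 UMIs per cell (x axis) after thinning each cell to 30000 UMIs, with a panel for each tumour and a dashed line above 4 UMIs. The KO tumours have 29.8% and 34.6% of cells at or below 4 UMIs and the WT tumours 2.0% and 1.7%.

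In Xist-low cells of the KO tumours some interferon-responsive, antigen presentation and chemokine genes rose and some glycolysis and hypoxia genes fell. Of 21 lists 13 passed with camera at the preset correlation and 0 with an estimated correlation (2 unadjusted). The greatest rises were in Cxcl11 (log2 fold change 2.67, standard error 0.18) and Cxcl10 (2.44, standard error 0.26), which encode chemokines that attract T cells through CXCR3. Cxcl10, on chromosome 5 from 92346638 to 92348889, rose from 139 and 233 CPM in the WT tumours to 1083 and 942 CPM in the KO tumours (adjusted p = 0.00969). Slfn2 (2.28), Csrnp1 (2.26) and Ptgs2 (2.11) rose and were most abundant in neutrophils, at 1227, 396 and 1041 CPM against 28.3, 30.9 and 67.3 CPM in Xist-low cells. Gja4 (2.07), Krt16 (1.99), Acta2 (1.87) and Socs1 (1.79), an inhibitor of cytokine signalling, also rose. Socs1, Cxcl11 and Cxcl10 were most abundant in neutrophils, at 173, 46.9 and 864 CPM against 68.5, 16.6 and 609 CPM in Xist-low cells. Acta2 was most abundant in fibroblasts (787 against 19.3 CPM). Gja4 and Krt16 were most abundant in Xist-low cells, at 42.1 and 19.0 CPM. Dcn, which encodes the proteoglycan decorin, fell most (log2 fold change -2.27, standard error 0.23, from 286 and 394 to 84 and 57 CPM). It was followed by Ankrd37 (-2.08), Medag (-2.07), Cela1 (-1.88), Gsn (-1.69), the fibronectin gene Fn1 (-1.68), Hist1h2bc (-1.62), Aldh3a1 (-1.61), Tenm4 (-1.59) and the osteopontin gene Spp1 (-1.58). Dcn, Gsn, Fn1 and Spp1 were most abundant in fibroblasts, at 3663, 1696, 2313 and 2447 CPM against 203, 308, 109 and 107 CPM in Xist-low cells. The 10 fibroblast markers summed to 1526 and 1991 CPM in Xist-low cells of the WT tumours and 905 and 547 CPM in those of the KO tumours. Gja4 and Krt16 are among the leading genes of cluster 1, and Dcn, Gsn and Aldh3a1 among those of cluster 0.

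By the fixed lists, the interferon-gamma response list had 5 of 25 measured members that rose and 20 that did not pass, among them Socs1 and Irf1 (1.19), a transcription factor of this response. Adjusted over the list alone, 11 rose. Of 7 T cell chemoattractants, 3 rose and 4 did not pass, with Cxcl11, Cxcl10 and Cxcl16 (0.88) as the called members and 7 rising when adjusted over the list alone. In the MHC class I list 8 of 20 rose and 12 did not pass, 14 rising when adjusted over the list alone. Called members were Psme1 (0.63) and Psme2 (0.80), subunits of the proteasome activator, and H2-Q7 (1.44) and H2-Q6 (1.78), whose near-identical sequences make the split of reads between them uncertain. H2-Q7 and H2-Q6 stood at 7.4 and 2.6 CPM in Xist-low cells and at 813 and 243 CPM in T and NK cells, and the call of H2-Q7 in Xist-low cells was lost after subtraction of free RNA (0.39, adjusted p = 0.41). The type I interferon list had 6 of 31 that rose and 25 that did not pass, 15 rising when adjusted over the list alone, with Rtp4 (1.16), Oas3 (1.31) and Isg15 (0.86). These 3 were most abundant in neutrophils, at 359, 188 and 1730 CPM against 28.6, 19.7 and 100 CPM in Xist-low cells. In the NF-kappaB list 8 of 17 rose and 9 did not pass, 16 rising when adjusted over the list alone, with Lif (1.55), Nfkb1 (0.81), and Nfkbia (1.28) and Tnfaip3 (1.12), which encode inhibitors of this pathway. Irf1 and Nfkbia were most abundant in neutrophils, at 743 and 4119 CPM against 288 and 817 CPM in Xist-low cells. Nfkb1 and Tnfaip3 were most abundant in T and NK cells (343 and 453 against 79.6 and 19.3 CPM), and Cxcl16 in mononuclear phagocytes (763 against 40.4 CPM). These lists passed with camera at adjusted p = 6.6e-14 for interferon-gamma, 6.53e-12 for T cell chemoattractants, 3.02e-10 for MHC class I, 4.65e-07 for type I interferon and 6.04e-12 for NF-kappaB. None passed when the correlation was estimated: adjusted p = 0.418, 0.265, 0.418, 0.418 and 0.265 with an estimated correlation, in that order. With 4 tumours that test has little power, so it cannot tell whether a list changed.

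**Figure D2:**
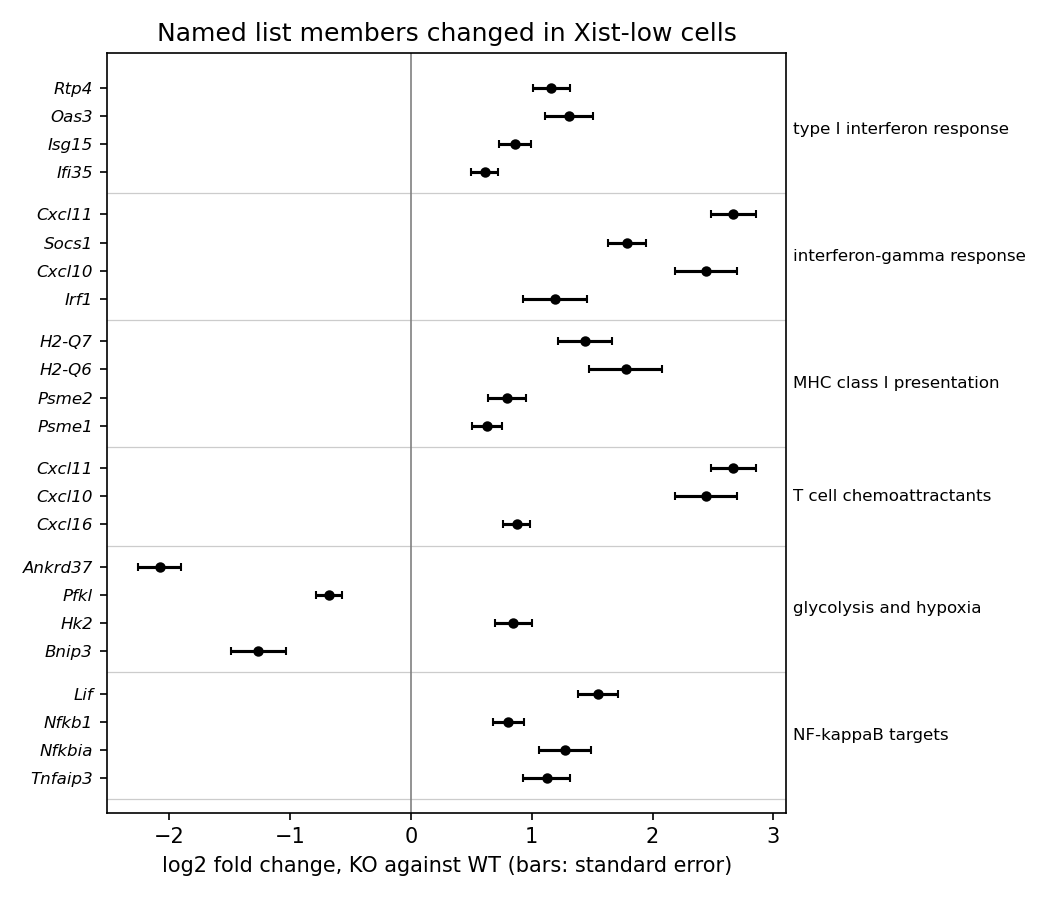
Log2 fold change of KO against WT tumours (x axis, bars are standard errors from edgeR, 2 tumours per group) for named members past the threshold of 6 gene lists in Xist-low cells. Cxcl11 and Cxcl10 lie at 2.67 and 2.44, and Ankrd37 at -2.08.

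Further lists in Xist-low cells passed with camera and none of them with an estimated correlation. MHC class II had 1 of 10 that rose (H2-DMb1, 0.50; 5 when adjusted over the list alone; camera adjusted p = 0.000748, adjusted p = 0.437 with an estimated correlation). Of 15 myeloid chemoattractants and growth factors, 2 rose, Cxcl1 (1.27) and Csf2 (2.23), and 11 when adjusted over the list alone (adjusted p = 2.16e-05, and 0.418 with an estimated correlation). Csf2, at 2.7 and 0.8 CPM in the WT tumours, ranged from 1.59 to 3.42 with a tumour left out. Of 20 immune inhibitory ligands and enzymes, 3 rose: Pvr (0.89), Ptgs2 and Cd274 (1.57), which encodes PD-L1. With a tumour left out Cd274 ranged from 1.07 to 2.33. Cd274 stood at 16.7 CPM in the class and 1180 CPM in neutrophils, and the call of Cd274 in Xist-low cells was lost after subtraction of free RNA (1.55, adjusted p = 0.0503, against 1.57 and 0.0444 before). Adjusted over the list alone, 7 rose (adjusted p = 8.87e-05, and 0.418 with an estimated correlation). The cell cycle list had 5 of 32 that rose, among them Tyms (0.57), Rrm2 (0.76) and Mcm5 (0.58), and 16 when adjusted over the list alone (adjusted p = 4.52e-06, and 0.418 with an estimated correlation). Ribosome biogenesis and Myc targets had 4 of 22 that rose, among them Rrp9 (0.76) and Srm (0.77), and 12 when adjusted over the list alone (adjusted p = 1.35e-06, and 0.488 with an estimated correlation). The stress response list had 3 that rose, Sesn2 (0.98), Sdf2l1 (0.47) and Manf (0.50), and 1 that fell, Ddit4 (-1.11), of 22, with 8 and 1 when adjusted over the list alone (adjusted p = 0.00736, and 0.418 with an estimated correlation). The immediate early list had 2 of 21 that rose, Socs3 (1.02) and Atf3 (1.22), with 6 that rose and 3 that fell when adjusted over the list alone (adjusted p = 0.0216, and 0.501 with an estimated correlation). Its call was lost after subtraction of free RNA (camera adjusted p = 0.097). The stress response and immediate early lists each lost the call with some tumour left out. Glycolysis and hypoxia went down, with 6 members that fell, among them Ankrd37, Pfkl (-0.68) and Bnip3 (-1.26), and 1 that rose, the hexokinase gene Hk2 (0.85), of 24. Adjusted over the list alone, 11 fell and 1 rose (adjusted p = 4.14e-05, and 0.418 with an estimated correlation).

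The other 8 lists did not pass with camera in Xist-low cells. Of 25 hnRNP family members other than Hnrnpa2b1, edgeR called 0, also when adjusted over the list alone (3 at an unadjusted p under 0.05; DESeq2 1), and Hnrnpa3 had the smallest p (log2 fold change 0.41, adjusted p = 0.0837; list adjusted p = 0.377). Of 16 nucleic acid sensing members edgeR called 0, also when adjusted over the list alone (3 unadjusted; DESeq2 1), with Irf7 at 0.48 (adjusted p = 0.0549; list adjusted p = 0.15). Of 21 m6A and microRNA processing genes 1 rose, Igf2bp1 (0.51; 0 when adjusted over the list alone; list adjusted p = 0.913), the list's median being 0.056, its mean -0.008 and its test direction down. Oxidative phosphorylation had 1 of 23 that rose, Cycs (0.72; 1 when adjusted over the list alone; list adjusted p = 0.0738). Epithelial identity had 1 that fell, Jup (-1.44), and 1 that rose, Krt19, at under 1 CPM in every tumour, of 5 measured (2 fell and 1 rose when adjusted over the list alone; list adjusted p = 0.247). Of 20 mesenchymal and matrix genes 3 rose, Thbs1 (2.12) among them, and 3 fell: Fn1, Snai2 (-0.84) and Zeb2 (-0.63; 4 rose and 4 fell when adjusted over the list alone; list adjusted p = 0.247). Thbs1 stood at 11.2 CPM in Xist-low cells and 2494 CPM in neutrophils. TGF-beta and YAP targets had Smad7 (0.82) rise and Id3 (-1.09) fall of 15 (2 and 3 when adjusted over the list alone; list adjusted p = 0.885). The p53 targets had Cdkn1a (0.77) rise and Rrm2b (-0.53) fall of 15 (5 and 3 when adjusted over the list alone; list adjusted p = 0.377).

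Over 17996 genes tested in Xist-low cells, 829 rose and 799 fell. Markers of other cell types moved within the class. Of CD8 T markers, 5 of 7 rose, at a summed 5.3 and 1.9 CPM in the WT tumours and 20.2 and 15.3 CPM in the KO tumours. Of 7 CD4 T markers 4 rose (4.9 and 1.8 against 17.5 and 13.9 CPM), and of 10 neutrophil markers 2 rose (13.9 and 13.4 against 38.4 and 20.5 CPM). Of 10 fibroblast markers 2, Dcn and Col3a1, fell. Free RNA was estimated at 12.4% and 6.39% of the UMIs of Xist-low cells in the WT tumours and 4.6% in each KO tumour. The count of 1628 changed genes became 3116 without WT tumour 1, 2940 without WT tumour 2, 609 without KO tumour 1 and 519 without KO tumour 2. It was 2664 with DESeq2 and 3902 without a filter on low counts.

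T and NK cells made up more of the KO tumours: 6.26% ± 0.37 of all cells in the WT tumours and 29.2% ± 0.731 in the KO tumours (SD, n = 2), 4.67 times as large (edgeR adjusted p = 0.0431). Within them, CD8 T cells were 11% ± 0.645 in the WT tumours and 39.2% ± 2.9 in the KO tumours (SD, n = 2; log2 ratio 1.83, standard error 0.29, edgeR adjusted p = 0.00146). CD4 T cells were 5.61% ± 2.73 and 17.2% ± 0.371 of T and NK cells (SD, n = 2; edgeR adjusted p = 0.00597), but at Leiden resolution 2.0 their log2 ratio was -0.70. At that resolution CD4 T cells of WT tumour 1 numbered 268, against 25 in the main clustering. A sub-cluster named CD4 T there drew 241 of 265 cells from WT tumour 1, doublets included, with a median of 1816 UMIs. Xist-low cells were 72.7% ± 4.19 and 23.1% ± 10.3 of all cells and mononuclear phagocytes 12.5% ± 0.337 and 31.2% ± 4.61 (SD, n = 2), neither past the threshold (edgeR adjusted p = 0.119 and 0.115).

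The remaining classes of all cells, neutrophils (1.96% and 6.44%), fibroblasts (2.19% and 3.65%), dendritic (0.638% and 1.49%), endothelial (0.331% and 0.751%), mural (0.165% and 0.585%), mast or basophil (0.177% and 0.172%) and unnamed cells (3.11% and 3.41%), did not pass. Of immune cells, T and NK cells were 29.1% ± 1.38 in the WT tumours and 42.9% ± 5.16 in the KO tumours (SD, n = 2; edgeR adjusted p = 0.373). Unnamed sub-clusters took 43.4% of T and NK cells in the WT tumours and 13.6% in the KO tumours (edgeR adjusted p = 0.00148). Of these, sub-cluster 0 drew 252 of 270 cells from WT tumour 1 and sub-cluster 16 drew 289 of 372 from WT tumour 2, doublets included, with few UMIs per cell. Over named T and NK cells alone, CD8 T cells were 19.6% and 45.4% (log2 ratio 1.21, standard error 0.10, edgeR adjusted p = 0.00536) and NK cells 37.8% and 21.9% (-0.79, standard error 0.033, edgeR adjusted p = 0.00199). The NK shares of the WT tumours, 37.83% and 37.87%, lie closer than counts of 160 and 128 cells would make likely. The standard error and p-value for NK cells may therefore be too small. CD4 T cells were 10.4% and 19.9% (edgeR adjusted p = 0.178), and regulatory T cells 19% and 7.46% and gamma-delta T cells 13.2% and 5.37% (edgeR adjusted p = 0.0802 for each).

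Without naming sub-clusters, the summed T and NK cells of the KO tumours held more RNA of Cd8a (log2 fold change 1.00, from 199 and 220 to 396 and 443 CPM, edgeR adjusted p = 0.0242) and Cd8b1 (0.87, adjusted p = 0.0323). They held less of the NK receptor gene Ncr1 (-0.91, adjusted p = 0.0326). Cd4 (0.24, adjusted p = 0.551) and the NK receptor gene Klrb1c (-0.40, adjusted p = 0.213) did not pass, nor did Cd3e (0.41), Foxp3 (-0.77) and Trdc (-0.42). Ifng, which encodes interferon-gamma, was 239 and 625 CPM against 288 and 357 CPM and did not pass (-0.42, standard error 0.37, adjusted p = 0.548). These 9 genes were chosen after the classes were seen. The call for T and NK cells among all cells was lost when any tumour was left out (adjusted p = 0.0786 without WT tumour 1, 0.0683 without WT tumour 2, 0.331 without KO tumour 1 and 0.232 without KO tumour 2). It was also lost over cells outside the Xist-low class (log2 ratio 0.73, adjusted p = 0.6). A replicate block and a crossed replicate block ended it too (2.22 in each, edgeR adjusted p = 0.404 and 0.0989). The call for CD8 T cells among T and NK cells was lost without KO tumour 1 (log2 ratio 1.75) and at Leiden resolution 2.0 (1.48, edgeR adjusted p = 0.135). That among named T and NK cells was lost likewise (1.15, adjusted p = 0.0683, and 1.28, adjusted p = 0.0671). CD4 T and unnamed cells among T and NK cells also lost their calls without KO tumour 1 (1.64 and -1.60, adjusted p = 0.0518 for each). So did CD4 T cells under the stricter cell filter (1.18, adjusted p = 0.0578), and NK cells among named cells at Leiden resolution 2.0 (-0.22, adjusted p = 0.355).

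**Figure D3:**
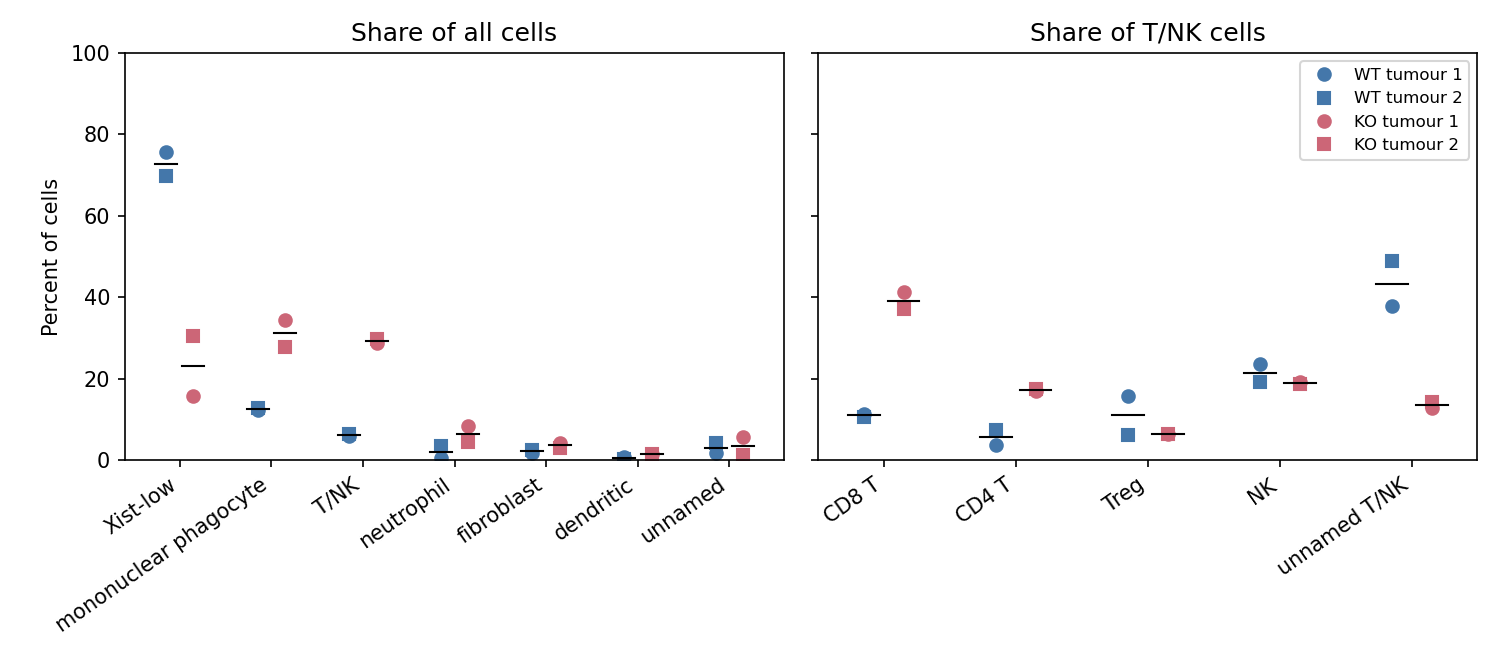
Percent of all cells (left) and of T and NK cells (right) in each named class, with a point for each tumour (blue WT, red KO; circle tumour 1, square tumour 2) and a bar at the group mean. T and NK cells average 6.26% of cells in the WT tumours and 29.2% in the KO tumours, and CD8 T cells 11% and 39.2% of T and NK cells.

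In mononuclear phagocytes of the KO tumours some type I interferon, NF-kappaB and lipid-handling genes rose, and Mgl2, Ccl17 and Ccl24, genes used as marks of alternative activation, fell. Of 17 lists 12 passed with camera at the preset correlation and 0 with an estimated correlation (0 unadjusted). Mgl2, a lectin gene on chromosome 11 from 70130329 to 70137550, fell from 158 and 147 CPM to 17.7 and 15.7 CPM (log2 fold change -3.19, standard error 0.18, edgeR adjusted p = 0.00247). Ccl24, which encodes an eosinophil-attracting chemokine, fell by 3.51 on the log2 scale, from 87.4 and 371 CPM to 16.7 and 23.4 CPM. Its log2 fold change ranged from -4.226 to -2.125 with a tumour left out. Tnnt2 (-3.01), Cavin3 (-2.67) and Cpe (-2.61) also fell; all 3 were more abundant in Xist-low cells. The greatest rises were in Ramp3 (2.34), the protease inhibitor gene Slpi (2.11), Ankrd33b (2.10), the growth factor gene Areg (1.99) and Il18bp (1.96), which encodes a binding protein of interleukin 18. After subtraction of free RNA 3 of the 1549 calls in the class were kept, Mgl2 among them. The risen genes named here then ranged from 1.59 for Il18bp in mononuclear phagocyte cells to 1.97 for Ramp3 in mononuclear phagocyte cells, with their calls lost, as were those of Ccl24, Ccl17 and Cpe, while Tnnt2 and Cavin3 had no value. At Leiden resolution 2.0 each gene named here lost its call, with log2 fold changes still from 1.75 for Il18bp to 2.25 for Ramp3 and from -2.42 for Cavin3 in mononuclear phagocyte cells to -3.88 for Ccl17 in mononuclear phagocyte cells. Cluster 7, led by Chil3, Spint1 and Gpr141 and with Mgl2 among its leading genes, held 69.9% and 49% of the class in the WT tumours and 7.2% and 9% in the KO tumours. Cluster 18, led by Nos2, Ly6i and Arg1, held 9.1% and 25.6% against 61.1% and 51.1%, and cluster 21, led by Ccl8, Apoe and Ms4a7, 4% and 4.8% against 19.8% and 30.9%. Cluster 15 stayed unnamed and lies outside the class. Its leading genes include Retnla, Clec10a, Mgl2 and Folr2, all of the alternatively activated list. It held 154 and 353 cells in the WT tumours and 374 and 61 in the KO tumours, so the falls above leave these cells out.

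The type I interferon list had 7 of 31 members that rose in mononuclear phagocytes, among them Rsad2 (1.79), Oasl1 (1.56) and Isg15 (0.91), and 10 when adjusted over the list alone. Rsad2, Oasl1 and Isg15 were most abundant in neutrophils, at 2022.5, 68.7 and 1730 CPM against 244, 31.3 and 241 CPM in phagocytes. NF-kappaB targets had 4 of 17 that rose, Traf1 (1.06), Nfkbie (1.14), Birc3 (0.96) and Tnf (0.96), and 11 when adjusted over the list alone. Of 20 MHC class I members 2 rose, H2-Q7 and H2-Q6 (3 when adjusted over the list alone), both most abundant in T and NK cells, and of 16 lipid-handling genes 6 rose, among them Ctsb (1.08), Plin2 (1.35) and Lipa (0.93; 8 when adjusted over the list alone). The inflammatory list had 4 of 15 that rose, Slamf7 (1.55), Tnf, Ptgs2 (1.15) and Cd86 (0.85; 6 when adjusted over the list alone). Of 24 interferon-gamma members edgeR called 0, also when adjusted over the list alone (9 at an unadjusted p under 0.05; DESeq2 5), and the list's call was lost without WT tumour 1 (adjusted p = 0.0932). In the cell cycle list 14 of 32 fell, among them Cenpf (-1.68), Cdc20 (-1.98) and Ube2c (-1.43), and 21 when adjusted over the list alone. These 3 genes were most abundant in Xist-low cells, at 316, 90.2 and 361 CPM against 63.2, 18.9 and 81.5 CPM in phagocytes, and free RNA was estimated at 27.4% and 20.8% of phagocyte UMIs in the WT tumours and 9.88% and 5.41% in the KO tumours. After subtraction of free RNA the calls of Cenpf in mononuclear phagocyte cells (-1.35, adjusted p = 0.399), Cdc20 in mononuclear phagocyte cells (-2.40, adjusted p = 0.269) and Ube2c in mononuclear phagocyte cells (-1.69, adjusted p = 0.258) were lost. The falls of Cdc20 and Ube2c were then larger in size than before, and that of Cenpf smaller. The alternatively activated list had 3 of 17 that fell, by either adjustment: Mgl2, Ccl17 (-3.91) and Ccl24. With camera, adjusted p = 7.33e-07 for type I interferon, 7.33e-07 for NF-kappaB, 4.19e-06 for MHC class I, 0.000114 for lipid handling, 7.23e-05 for the inflammatory list, 0.000385 for interferon-gamma, 8.15e-12 for cell cycle and 0.00606 for alternative activation. With an estimated correlation the adjusted p was 0.517 for type I interferon, 0.63 for interferon-gamma and 0.509 for the other 6. After subtraction of free RNA these lists still passed with camera at the preset correlation. The adjusted p was then 2.43e-06 for cell cycle, and ranged from 4.52e-11 for alternative activation to 0.0147 for interferon-gamma.

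Another 4 lists passed upward with camera in mononuclear phagocytes. None of them passed after subtraction of free RNA (camera adjusted p = 0.395, 0.746, 0.746 and 0.261, in the order below). All but the T cell chemoattractants also lost the call with some tumour left out. Of 7 T cell chemoattractants 1 rose, Cxcl16 (0.86; 2 when adjusted over the list alone; adjusted p = 0.0176, and 0.509 with an estimated correlation). Of 19 immune inhibitory genes 3 rose, Entpd1 (0.96), Pvr (0.79) and Ptgs2 (4 when adjusted over the list alone; adjusted p = 0.0328, and 0.509 with an estimated correlation). Of 13 complement and tissue macrophage genes, Mertk (0.92), Selenop (0.98) and Adgre1 (0.78) rose and Axl (-1.10) fell (4 and 2 when adjusted over the list alone; adjusted p = 0.0382, and 0.509 with an estimated correlation). Of 13 monocyte genes 2 rose, Thbs1 (1.71) and Ly6a (1.15; 3 when adjusted over the list alone; adjusted p = 0.0328, and 0.63 with an estimated correlation). The other 5 lists did not pass. In MHC class II edgeR called 0 of 11, also over the list alone, with 1 unadjusted and 1 by DESeq2, and Ciita stood at -0.70 (list adjusted p = 0.812, median 0.051 and mean -0.031). Of 13 myeloid chemoattractants Il34 (-2.59) fell, by either adjustment (adjusted p = 0.812, median 0.134 and test direction down). Il34 was most abundant in Xist-low cells, at 58.8 CPM against 9.7 CPM in phagocytes. Of 24 glycolysis and hypoxia genes Vegfa (1.10) rose and Ankrd37 (-1.34) fell, by either adjustment (adjusted p = 0.361). In oxidative phosphorylation edgeR called 0 of 23, also over the list alone, with 1 unadjusted and 0 by DESeq2, Ndufa4 standing at -0.47 (adjusted p = 0.812). Of 21 immediate early genes Ier2 (-1.01) fell, by either adjustment (adjusted p = 0.651).

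Over 13520 genes tested in mononuclear phagocytes, 668 rose and 881 fell with edgeR. As to free RNA, 96.3% of the genes that fell were more abundant in the whole WT libraries than in WT phagocytes, against 61.6% of all genes tested. Of the genes that rose, 83.4% were less abundant in the libraries, against 38.4% of all genes tested. The median log2 fold change of these 557 risen genes went from 1.09 to 0.76 after subtraction of free RNA. For all tested genes less abundant in the libraries it went from 0.315 to 0.045. For these rises, too, free RNA cannot be told apart from a change in the cells. Of 10 neutrophil markers 1 rose in the class, the 10 summing to 357 and 643 CPM in the WT tumours and 1198 and 925 CPM in the KO tumours. The count of 1549 became 4 after subtraction of free RNA, 2 without low-UMI clusters, 0 at Leiden resolution 2.0 (edgeR, 2807 at an unadjusted p under 0.05; DESeq2 on the main classes called 1463). It was 8 without WT tumour 1, 3379 without WT tumour 2, 984 without KO tumour 1 and 3111 without a filter on low counts. Of the 1549 genes, 1113 were still tested after subtraction of free RNA, and 95.7% of these had the same sign, the median ratio of the log2 fold change to that before being 0.761. Without low-UMI clusters, at Leiden resolution 2.0 and without WT tumour 1, 100% of the 1449, 1520 and 1528 still tested had the same sign, with median ratios of 0.815, 0.915 and 0.902, so calls were lost far more than size.

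In CD8 T cells of the KO tumours the granule protease gene Gzma and 10 of 32 cell cycle genes fell, the cell cycle list being at adjusted p = 0.532 with an estimated correlation. Without either KO tumour edgeR called 0 genes in the class (388 and 501 unadjusted; DESeq2 on all tumours 115). The class held 78 and 70 cells in the WT tumours and 1024 and 969 in the KO tumours. Gzma, on chromosome 13 from 113093825 to 113100981, fell from 1419 and 2689 CPM to 575 and 615 CPM (log2 fold change -1.79, standard error 0.28, edgeR adjusted p = 0.0219). The greatest falls were in the chemokine gene Xcl1 (-2.30), Hist1h4h (-2.16), Nupr1 (-2.13), Hist1h1b (-2.13) and Gadd45g (-2.01), and the greatest rises in Gpcpd1 (3.39), Nt5e (2.34), which encodes the ectoenzyme CD73, Mirt1 (2.09), Mxd4 (1.96) and Gramd3 (1.95). With a tumour left out Xcl1 ranged from -3.475 to -1.586 and Mirt1 from 1.31 to 3.38, so their ranks are unsure. Sub-cluster 2, led by the proliferation genes Pclaf, Nusap1 and Mki67, held 64.1% and 27.1% of CD8 T cells in the WT tumours and 14.9% and 13.7% in the KO tumours. Sub-cluster 11, led by Ccl3, Serpine2 and Zbtb32, held 15.4% and 44.3% against 44.8% and 52.7%, and sub-cluster 14, led by Gzmk, Ly6c2 and Cd8b1, 12.8% and 20% against 34.6% and 28.3%.

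In the cell cycle list 10 of 32 fell in CD8 T cells, among them Tpx2 (-1.71), Cenpe (-1.53) and Nusap1 (-1.50), and 23 when adjusted over the list alone (camera adjusted p = 3.86e-25, and adjusted p = 0.532 with an estimated correlation). Also past the threshold with camera, and at adjusted p = 0.532 with an estimated correlation, were 6 lists with at most 1 called member each. None of the 6 passed after subtraction of free RNA (camera adjusted p from 0.0632 to 0.457), and fewer lists passed whichever tumour was left out. Upward were interferon-gamma (edgeR called 0 of 21, also over the list alone, with 2 unadjusted and 0 by DESeq2; Cd274 at 1.10; adjusted p = 0.0283), naive and memory-like (adjusted p = 0.0283) and exhaustion (adjusted p = 0.0397). In the naive and memory-like list the called member of 13, Xcl1, fell, and 6 rose and 2 fell when adjusted over the list alone. In the exhaustion list the called member of 16, the receptor gene Cd244a (-3.02), fell, and 2 rose and 1 fell when adjusted over the list alone. Downward were the immediate early list (Fos, -1.38, fell, of 20; 3 when adjusted over the list alone; adjusted p = 0.0283), oxidative phosphorylation (adjusted p = 0.0397) and glycolysis and hypoxia (adjusted p = 0.0451). In oxidative phosphorylation edgeR called 0 of 23, also over the list alone, with 1 unadjusted and 0 by DESeq2, and Ndufa5 stood at -0.54. In glycolysis and hypoxia it called 0 of 22, also over the list alone, with 4 unadjusted and 0 by DESeq2, and Ldha stood at -0.62. Cytotoxicity did not pass (Gzma fell, of 19; 3 rose and 3 fell when adjusted over the list alone; adjusted p = 0.0529), its median being 0.418, its mean -0.016 and its test direction up. Nor did T cell activation (edgeR called 0 of 12, with 4 unadjusted and 0 by DESeq2; Icos at 1.33, 1 rose when adjusted over the list alone; adjusted p = 0.145). In the type I interferon list, which did not pass either, edgeR called 0 of 27 (also over the list alone, with 5 unadjusted and 0 by DESeq2; Trim30a at 0.81; adjusted p = 0.382).

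Over 10354 genes tested in CD8 T cells, 48 rose and 57 fell with edgeR, and 1813 had an unadjusted p under 0.05. Of 7 NK markers 3 fell, at a summed 2124 and 3417 CPM in the WT tumours and 1272 and 1361 CPM in the KO tumours. Gzma is among these markers and alone held 1419 and 2689 against 575 and 615 CPM. The lower sums therefore do not show a fall of NK markers apart from Gzma. Of 11 macrophage markers 1 rose, at a summed 289 and 227 against 632 and 602 CPM. The call of Gzma in CD8 T cells was lost without KO tumour 1 (log2 fold change -1.73, adjusted p = 0.529), without KO tumour 2 (-1.82, adjusted p = 0.485) and at Leiden resolution 2.0 (-1.62, adjusted p = 0.0842). It was kept without WT tumour 1 (-2.12) and without WT tumour 2 (-1.20). The count of 105 became 53 without WT tumour 1, 925 without WT tumour 2 and 0 without either KO tumour. It was 1 at Leiden resolution 2.0, 1 with 70 cells drawn from each tumour, 45 under the stricter cell filter, 67 after subtraction of free RNA and 624 without a filter on low counts. Of the 105 genes, those still tested had the same sign in each of these settings, with a median ratio of the log2 fold change to the main one of 1.002 without KO tumour 1, 0.994 without KO tumour 2, 0.91 at Leiden resolution 2.0 and 0.938 with equal cells.

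In other classes, 163 genes rose and 117 fell in T and NK cells together and 266 rose and 270 fell in NK cells. In fibroblasts edgeR called 0 genes (1476 at an unadjusted p under 0.05) and DESeq2 134, and in neutrophils edgeR called 0 (664 unadjusted) and DESeq2 0.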

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

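Tests chosen after the result was seen were the split of cells at 4 Hnrnpa2b1 UMIs, the count of cells with none at 30000 UMIs, the subtraction of free RNA from phagocyte sums, the comparison of UMIs per cell between classes, leaving out low-UMI clusters and the test of differences between classes.

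The change between KO and WT tumours differed between Xist-low cells and mononuclear phagocytes for 2750 of 17362 genes by an edgeR interaction test with the tumour as a block. It did so for 52 of the 106 genes named in either class and measured in both, a higher share to be expected of genes most of which were named for a change in a class. Of the 106, 3 were called in both with opposite signs. Id3, which encodes an inhibitor of helix-loop-helix transcription factors, differed by -1.91 on the log2 scale, Xist-low minus phagocyte (standard error 0.20, edgeR adjusted p = 0.00056), being -1.09 in Xist-low cells and 0.87 in phagocytes. Lipa, which encodes lysosomal acid lipase, differed by -1.43 (standard error 0.16, adjusted p = 0.000662), being -0.55 and 0.93. Rrm2, a subunit of ribonucleotide reductase, differed by 1.82 (standard error 0.21, adjusted p = 0.00073), being 0.76 and -1.01. Rrm2 stood at 18.7 CPM in phagocytes and 81.1 CPM in Xist-low cells, whose RNA is in the free RNA that WT phagocytes held more of. After subtraction of free RNA the calls of Rrm2 in mononuclear phagocyte cells (-1.25, edgeR adjusted p = 0.299) and Lipa in mononuclear phagocyte cells (0.65, adjusted p = 0.293) were lost, and the differences between classes were not tested again.

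Hnrnpa2b1 RNA was left in Xist-low cells of the KO tumours at 0.613 times the WT level. Free RNA of other cells was argued against, since the estimated free RNA accounted for at most 4.92% of the level in a KO tumour, under the 25% written beforehand. A mixture of unedited cells and edited cells with no Hnrnpa2b1 RNA met neither bound written beforehand (under 10%, or at least 20%, in both KO tumours), since at 10000 UMIs 14.8% of cells in KO tumour 1 and 22.29% in KO tumour 2 had no Hnrnpa2b1 UMI, although the mixture would need 38.3%. It was argued against at 30000 UMIs, where 4.08% and 6.79% had none (exact binomial upper 95% bounds 5.59% and 8.2%), the estimated free RNA would leave 17.0% and 21.8%, and it would have to be 3.54 and 3.52 times as high to leave so few. Cells of 2 kinds, of which the first holds little and not no Hnrnpa2b1 RNA, had the values they need, with 29.8% and 34.6% of deep cells at 4 UMIs or fewer in the KO tumours and 2.0% and 1.7% in the WT tumours, at a boundary set on the same data, so the KO tumours may hold cells in which the gene was not edited, and edited cells whose transcript persists at a low level, which was not tested.

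Most genes that fell in mononuclear phagocytes of the KO tumours were more abundant in the whole WT libraries than in WT phagocytes (848 genes, 96.3%), and WT phagocytes held more free RNA. For these genes free RNA cannot be told apart from a change in the cells, since over the 418 that still had a value after subtraction the median log2 fold change went from -1.32 to -0.93, 70.6% of its size. Genes less abundant in the libraries made up 3.7% of those that fell, a low share as free RNA would need. Free RNA would not give the fall of these 33 genes themselves, with a median, over the 32 that still had a value, of -1.72 before subtraction and -2.18 after it, Mgl2 in mononuclear phagocyte cells standing at -3.67 (edgeR adjusted p = 0.0224). The makeup of the class differed between the groups, cluster 7 holding 69.9% and 49% of it in the WT tumours and 7.2% and 9% in the KO tumours. Whether this difference gives the falls stays open and was not tested.

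Xist-low cells held 2.97 times as many UMIs per cell, by median, in the KO tumours as in the WT tumours. Library depth as the whole cause was argued against, since this ratio was 1.81 times that of mononuclear phagocytes in the same libraries (1.65), above the bound of 1.5. A larger share of low-UMI cells in the WT tumours was argued against too, the ratio being 2.846 without low-UMI clusters, above the bound of 2 written beforehand. A larger RNA content of the cells that make up the class in KO tumours, and a difference in how these cells were captured, stay open and untested.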

How the results depend on the processing

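The tests chosen after the data were seen in this part are the subtraction of free RNA, leaving out low-UMI clusters, the mixed fry test and the crossed pairing; the others were set beforehand. Across settings, named genes kept direction and side of the threshold in 1714 results, lost the call in 379, gained it in 28 and turned in 0. Shares kept both in 193, lost the call in 17, gained it in 12 and turned in 21. Lists kept both in 338, lost the call in 102, gained it in 14 and turned in 26. Hnrnpa2b1 in Xist-low cells ranged from -0.78 to -0.63 when each tumour was left out, and the call was lost without either KO tumour. With a tumour left out, the lone tumour of its group is assumed to vary like the other group. Except where stated, the cause of a change was not tested.

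The count of changed genes in Xist-low cells, 1628, was 2664 with DESeq2, 3902 without a filter on low counts and 519 to 3116 with a tumour left out. In mononuclear phagocytes the count of 1549 was 0 at Leiden resolution 2.0 (edgeR, 2807 unadjusted; DESeq2 on the main classes 1463), 4 after subtraction of free RNA, 2 without low-UMI clusters, 3111 without the filter and 8 to 3379 with a tumour left out. In CD8 T cells the count of 105 was 1 at Leiden resolution 2.0, 1 with equal cells (70 per tumour, so fewer UMIs and 4968 genes tested), 45 under the stricter cell filter, 67 after subtraction of free RNA, 624 without the filter and 0 to 925 with a tumour left out (at 0, edgeR had 388 and 501 unadjusted; DESeq2 on all tumours called 115). Of genes called at first, 0 were called in the opposite direction in any of these settings. Among those still tested, the median ratio of the log2 fold change to the main one was, in phagocytes, 0.915 at Leiden resolution 2.0, 0.761 after subtraction of free RNA, 0.815 without low-UMI clusters and 0.902 without WT tumour 1. In CD8 T cells it was 0.91 at Leiden resolution 2.0, 0.938 with equal cells, and 1.002 and 0.994 without KO tumour 1 and 2. In CD8 T cells the median log2 fold change with DESeq2 was -0.287, over every gene with a UMI in the class. With edgeR it was 0.03, over the 10354 genes past its filter on low counts, so these medians cannot be compared. Over the 105 genes called at first, the median ratio of the DESeq2 log2 fold change to the main one was 0.995. In NK cells the count was 536 with edgeR and 159 with DESeq2, and in fibroblasts 0 (1476 unadjusted) and 134.

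Gene lists past the threshold numbered 13 in Xist-low cells, 12 in mononuclear phagocytes and 7 in CD8 T cells. With an estimated correlation and with the directional fry test, each class had 0 (limma, with 2, 0 and 0 lists at an unadjusted p under 0.05 in camera and 4, 1 and 0 in fry). Both have little power with 4 tumours, so a list that fails them is left undecided. By the mixed fry test, which reads change in either direction and compares with no other genes, 13, 5 and 0 passed (17, 10 and 1 unadjusted). After subtraction of free RNA 14 lists passed with camera in Xist-low cells and 9 in mononuclear phagocytes. In CD8 T cells 1 list passed after subtraction of free RNA and 1 to 6 with a tumour left out. After subtraction of free RNA the direction turned for MHC class II (adjusted p = 0.0112, now down), glycolysis and hypoxia (0.957), immediate early (0.904), myeloid chemoattractants (0.888) and oxidative phosphorylation (0.384) in phagocytes, and for TGF-beta and YAP targets (0.789) and m6A processing (0.789) in Xist-low cells. Without low-UMI clusters it turned for MHC class II (0.157) and list myeloid chemoattractants and growth factors in mononuclear phagocyte cells (0.879).

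With a tumour left out, list directions turned at least once, with adjusted p ranging in phagocytes from 0.31 to 0.918 for MHC class II, 0.0931 to 0.989 for immediate early, 0.458 to 0.774 for myeloid chemoattractants and 0.00942 to 0.918 for oxidative phosphorylation. In CD8 T cells the ranges were 8.84e-06 to 0.719 for activation, 0.0124 to 0.283 for cytotoxicity, 5.4e-06 to 0.853 for exhaustion, 1.01e-06 to 0.951 for immediate early and 0.177 to 0.719 for type I interferon. In Xist-low cells they were 0.611 to 0.98 for TGF-beta and YAP targets, 0.107 to 0.93 for epithelial identity, 0.793 to 0.98 for m6A processing and 0.01 to 0.808 for mesenchymal identity.

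Shares are given as log2 ratios. T and NK cells of all cells ranged from 2.16 to 2.28 with a tumour left out, never past the threshold, and were 0.73 (adjusted p = 0.6) over cells outside the Xist-low class. Over those cells mononuclear phagocytes (-0.19), dendritic (-0.32), endothelial (-0.35), fibroblast (-0.75) and unnamed cells (-1.39) turned, their denominator having changed. T and NK cells of immune cells passed under the stricter cell filter (0.91, adjusted p = 0.0356). At Leiden resolution 2.0 CD8 T cells were 1.48 of T and NK cells and 1.28 of named ones, neither past the threshold, and CD4 T cells turned to -0.70 and -0.73. The turn went with the naming as CD4 T of a sub-cluster drawn mostly from WT tumour 1. With a tumour left out CD8 T cells ranged from 1.75 to 1.91 and from 1.13 to 1.30. Keeping doublets turned mast or basophil cells of all cells to 0.43. Leaving out a tumour turned regulatory T cells of T and NK cells (-1.30 to 0.025), dendritic cells of immune cells (-0.98 to 0.30), mast or basophil cells of all (-0.99 to 3.95) and of immune cells (-2.77 to 2.52), neutrophils of immune cells (-0.70 to 2.03) and unnamed cells of all (-1.37 to 0.86).

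The tumour numbers 1 and 2 are shared by both groups, and the labels do not say that they pair tumours. Deviations from the group means of same-numbered tumours correlated across genes at -0.48 in Xist-low cells, -0.443 in phagocytes and -0.087 in CD8 T cells. With the number as a replicate block, the counts were 1774, 2097 and 181, Hnrnpa2b1 in Xist-low cells was -0.71 (adjusted p = 0.0501), T and NK cells of all cells 2.22 (adjusted p = 0.404), mast or basophil cells 0.88 and unnamed cells -0.13, and the phagocyte list of myeloid chemoattractants turned (adjusted p = 0.933). The block ended calls of 13 named genes, Hnrnpa2b1 among them, 1 list, T and NK cells of all cells and CD4 T cells of T and NK cells, and added calls of 2 named genes and 2 lists. With the numbers crossed, the counts were 4506, 3260 and 176, and the shares of T and NK, mast or basophil and unnamed cells 2.22 (adjusted p = 0.0989, the call lost), 0.59 and -0.13.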

Other observations

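The test in this part that compares cells with little and with more Hnrnpa2b1 RNA, and the choice of genes and clusters named here, were made after the data were seen. The bounds of that test were written before its result.

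NK cells differed between the groups in genes outside the fixed lists. Over 8587 genes tested, 266 rose and 270 fell in the KO tumours (edgeR), with 159 called by DESeq2. Il7r, which encodes the interleukin 7 receptor alpha chain, rose from 38.4 and 61.7 CPM in the WT tumours to 248 and 249 CPM in the KO tumours (log2 fold change 2.35, standard error 0.24, adjusted p = 3.6e-05). Rora (2.15), a nuclear receptor gene, and Stat3 (1.32), a transcription factor gene, also rose. Different sub-clusters held NK cells in the groups. Sub-cluster 4, led by Klra8, Ncr1 and Gzma, had 119 and 82 cells from the WT tumours and 4 and 11 from the KO tumours, doublets included. Sub-cluster 5, led by Klra8, Klra4 and Klra13-ps, had 4 and 19 against 270 and 305. Gsn, most abundant in fibroblasts among the classes compared for Xist-low cells, fell in NK cells from 103 and 92.6 CPM to 29 and 22 CPM.

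Cluster 15, led by Retnla, Ear2 and Lyz1, with Clec10a, Mgl2 and Folr2 among its leading genes, stayed unnamed, because its leading genes held more markers of another class than of macrophages. The sums of mononuclear phagocytes therefore leave it out. Cluster 15 held 1.36% and 3.47% of cells in the WT tumours (154 and 353 cells) and 4.32% and 0.7% in the KO tumours (374 and 61 cells), so the spread within each group was larger than the difference between them.

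A hypothesis was that the genes changed between KO and WT Xist-low cells follow the loss of Hnrnpa2b1 RNA in the same cells. Within the KO tumours, cells with at most 4 Hnrnpa2b1 UMIs were compared with cells with at least 8, after thinning to 30000 UMIs, with the tumour as a block. Of 1501 genes changed between the groups and compared here, 842 (56.1%) differed in the same direction, and the median difference in that direction was 0.02 against a median size of 0.85, or 2.1%, under the 10% written beforehand as evidence against the hypothesis. Of 14821 genes, 78 were called, 50 higher and 28 lower in cells with little Hnrnpa2b1 RNA (1330 unadjusted). The 28 include Hnrnpa2b1 itself (-2.85), by which the cells were split and which the 1501 leave out. The higher genes include Ifit1 (0.60), Ifit3 (0.66), Ccl2 (0.23) and Cxcl1 (0.23), and also Crabp2 (0.22), Prelp (0.36) and Slurp1 (0.22). The lower ones include Malat1 (-0.215), Cenpe (-0.22), Ncl (-0.11) and Hnrnph1 (-0.16). No gene list was tested in this comparison. UMIs of Hnrnpa2b1 do not measure its protein, so cells with more RNA may also lack the protein, in which case this comparison would show little.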
